A study of Mus musculus with 8 samples.

How the data were processed

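RNA from sorted monocyte-derived dendritic cells was sequenced in 8 libraries, 4 per group, each from a separate pool of mice. Per the labels, cells were sorted as CD45-high, CD11b-positive, Ly6G-negative, Ly6C-positive, CD11c-intermediate and MHC class II-positive after collagenase digestion (0.2 mg/ml, 30 minutes) and a density gradient. RNA integrity numbers were at least 8, cDNA was amplified with the Ovation RNA-Seq V2 kit, libraries had 12 PCR cycles, and single-end reads of 150 bases came from a NextSeq 500. Per the submitters' processing notes, the tools were Trimmomatic, STAR 2.3.0, HTSeq 0.5.3 and limma, with the mouse build mm10. The gene annotation, the strand setting of the counting and any filter on low genes are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

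The authors deposited log2 normalised expression values for 12256 genes, 1 column per library, not divided by gene length. The linear values are (whole number + 0.5) multiplied by 1 step per library, and 100% of them came out whole within a tolerance of 0.01, which is the form limma voom gives (log2 of reads per 1000000 of a scaled library). Whole reads and scaled library sizes (2.56 to 19.6, in units of 1000000 reads) were recovered from these steps; they served for depth, for thinning and for voom weights, while the main tests used the log2 values as deposited. All columns were used. Because the offset of 0.5 reads is worth more in a shallow library, low genes have higher floors in the NPC libraries, which can raise their NPC values over PBS: 6.81 to 22.4% of genes had under 10 reads there and 0.579 to 4.49% in the PBS libraries. PCR duplicates cannot be removed from such a table, so reads are not independent molecules. The least different pair of libraries had a chi-square of 5.22 per degree of freedom, so no pair agreed within counting error; repeat preparations of 1 sample could exceed it too.

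Groups were taken from the sample titles. Each gene was tested with limma 3.58.1 in R 4.3.3 (linear model with treatment as the only term, moderated variances with a mean-variance trend, two-sided, Benjamini-Hochberg over all genes, threshold 0.05). Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and adjusted over 37 lists; camera with an estimated correlation, fry and an exact permutation of list means (70 arrangements) stand beside it. Principal components used gene-centred log2 values, and single values per library were compared by exact two-sided permutation. Values are given as mean ± SD on the log2 scale and fold changes as NPC minus PBS on that scale. Coordinates, transcript length and GC content came from GENCODE vM21 by gene symbol; 11368 of 12256 symbols (92.8%) matched 1 gene, 21 matched more than 1 and 867 none. Plots were drawn with matplotlib 3.10.9.

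The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were up to 12 per direction past the threshold; where fewer than 5 passed, the 8 with the smallest unadjusted p per direction and non-overlapping groups; up to 4 members of each function list and 2 of each control list by smallest p; 7 genes of the sort; and 17 genes of TGF-β and inflammation. A few genes that this rule selects are not reported here. Fos and other genes given per library for PBS 1 and NPC A, and the T cell receptor genes, were chosen after their values or those of related genes were seen. The alternatives fixed in advance were no variance trend, a robust prior, library weights, quantile normalization, equal medians, 2 filters on low genes, 1 added on the linear scale, a residual component as covariate, other thresholds, and leaving out each library. Added after seeing the data were voom weights, thinning to the shallowest scaled library (2.56 in those units), a spline correction of each library for GC content and transcript length (11368 genes), leaving out PBS 1 and NPC A together, and exact permutation of list means.

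The pipeline was tested on simulated reads for the 12256 genes of this comparison, with the real means, depths and spread and 200 changed genes in each of 10 simulations. It recovered 24.4% of genes changed 1.5-fold, 67.0% at 2-fold, 88.0% at 3-fold and 93.8% at 4-fold, with 6.8 false calls among 143.4 on average. Without any change it made 0.1 gene calls and 0.1 list calls on average; the simulated genes varied independently, which real genes do not.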

Results

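RNA was sequenced from monocyte-derived dendritic cells of the inflamed central nervous system, in order to compare mice given neural precursor cells with mice given vehicle. The mice were C57Bl/6 animals with experimental autoimmune encephalomyelitis (EAE), an autoimmune disease raised here with a myelin oligodendrocyte glycoprotein peptide (residues 35 to 55). At the peak of disease, 2 to 4 days after clinical onset, they received PBS or 1000000 neural precursor cells into the cerebrospinal fluid. Cells were sorted from hindbrain and spinal cord 7 days later. Each group held 4 libraries, and each library came from a separate pool of 4 to 7 mice. The PBS libraries are named 1 to 4 and the neural precursor cell (NPC) libraries A to D, and nothing in the labels pairs them. The table held 12256 genes. The reads behind the PBS libraries numbered 15746650, 21068166, 7702189 and 9997184, and those behind NPC A to D numbered 3962743, 2653818, 3336214 and 7003542. The PBS libraries were on average 3.21 times as deep (n = 4 each), with no overlap between the groups (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow), so depth differed together with treatment. The median gene had 37 to 93 reads in the NPC libraries and 129 to 281 in the PBS libraries.

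The surface proteins that defined the sort were transcribed at closely similar levels in both groups. Ptprc, which encodes CD45, was at 9.71 ± 0.12 log2 normalised expression in PBS and 9.73 ± 0.25 in NPC libraries (SD, n = 4 each). Itgam, encoding CD11b, was at 10.56 ± 0.20 and 10.51 ± 0.45. Itgax, encoding CD11c, was at 7.38 ± 0.08 and 7.32 ± 0.29, and the class II gene H2-Ab1 at 11.91 ± 0.17 and 11.96 ± 0.27. Ly6c2 was at 8.64 ± 0.31 and 8.53 ± 0.28. None of these 5 genes passed the test between groups, and the 95% interval of each log2 fold change lay between -0.51 and 0.47. Ly6c1 and Ly6g are not in the table used here.

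The largest difference between libraries did not follow treatment. The first principal component held 31.9% of the variance and set PBS 1 (score -36.2) and NPC A (score -44.3) apart from the other 6 libraries (1.98 to 26.0), with no difference between groups (exact two-sided permutation p = 0.83). The second held 20.1% of the variance (exact p = 0.286). Without NPC B, however, the groups parted on the second component at the smallest p that the remaining libraries allow. In PBS 1 and NPC A the 31 immediate-early and heat-shock genes, which cells switch on within minutes of a stimulus or stress, averaged 5.74 and 5.69, against 7.05 to 7.47 in the other 6 libraries. Fos, a subunit of the AP-1 transcription factor, was at 7.95 in PBS 1 and 8.28 in NPC A and at 9.65 to 10.18 elsewhere. Mitochondrially encoded transcripts made up 18.6% of the reads in PBS 3 and 33.8 to 34.8% in the other PBS libraries, against 25.2 to 33.9% in the NPC libraries. Pairwise Pearson correlations between libraries, across genes, ran from 0.946 to 0.987.

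**Figure D1:**
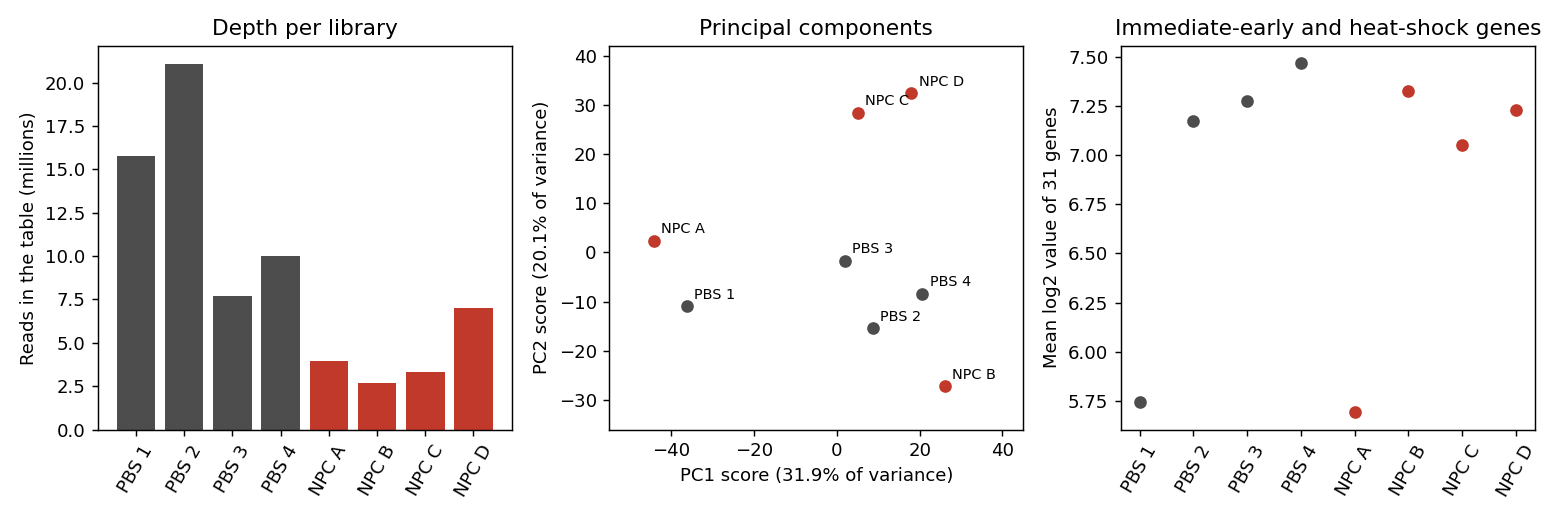
Reads per library (left, bars, axis in units of 1000000 reads), scores on the first 2 principal components (middle) and the mean log2 normalised expression of 31 immediate-early and heat-shock genes (right, 1 point per library), with PBS libraries in grey and NPC libraries in red. All 4 NPC libraries were shallower than every PBS library, and PBS 1 and NPC A stood apart on the first component and had the lowest immediate-early means, 5.74 and 5.69.

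Which genes differed between dendritic cells of NPC-treated and PBS-treated mice was asked first gene by gene. No gene passed the threshold: 0 of 12256 had an adjusted p under 0.05 in limma's moderated test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.382. At an unadjusted p under 0.05 there were 1387 genes, 735 higher and 652 lower in NPC libraries, where chance alone gives 613 on average. Genes vary together, so that count spreads widely. The 35 splits of the 8 libraries into 4 and 4 gave a median of 484, and the highest split other than the real one gave 1561. That highest split put PBS 1 and NPC A, with NPC C and NPC D, on one side. Of the 35 splits, 2 gave at least 1387, the real one among them. The excess over 613 therefore does not by itself tell treatment from chance. With limma voom weights on the recovered reads, 0 genes passed and 1576 had an unadjusted p under 0.05. The groups did not overlap for 831 genes (433 higher, 398 lower), which is 6.78% of genes. Chance gives 2.86% on average, and no spread was computed for this share.

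The genes with the smallest unadjusted p and non-overlapping groups are given as values, since none passed. Among those higher in NPC libraries, Tet1, which encodes a DNA 5-methylcytosine dioxygenase, was at 2.91 ± 0.09 against 1.74 ± 0.22 in PBS (log2 fold change 1.17, SE 0.20; n = 4 each). Prkdc, the catalytic subunit of DNA-dependent protein kinase, was at 5.96 ± 0.14 against 5.31 ± 0.09 (0.64, SE 0.11). Gpr82, an orphan receptor gene, stood at 2.10 ± 0.23 against 0.74 ± 0.33 (1.36, SE 0.27), resting on 11 to 42 reads per library. Elmo1, a regulator of Rac during engulfment and migration, was at 6.50 ± 0.08 against 5.99 ± 0.10 (0.51, SE 0.11). Values also stood higher for 9930111J21Rik2 (0.58), Eps15l1 (0.55) and 2810055G20Rik (1.14). Among those lower, Lgals1, which encodes the lectin galectin-1, was at 5.25 ± 0.22 against 5.89 ± 0.10 (-0.64, SE 0.13). Cotl1, encoding an actin-binding protein, was at 5.33 ± 0.15 against 5.89 ± 0.14 (-0.56, SE 0.12), and Cndp2, a cytosolic dipeptidase gene, at 6.63 ± 0.18 against 7.24 ± 0.22 (-0.61, SE 0.14). Usf2 (-0.62), Bahd1 (-0.70), Cuedc2 (-0.76), Ubxn1 (-0.63) and Gm24270 (-0.74), annotated as a microRNA gene 57 bases long, completed the 8. The adjusted p was 0.382 for each gene named here. Fold changes followed transcript GC content and length across 11368 genes (Spearman rho -0.368 and 0.212), and the genes named here mostly followed GC too. Transcript GC was 43.7% for Tet1, 43.3% for Prkdc, 46.9% for Elmo1 and lower still for Gpr82, with 51.8% for Eps15l1 the highest of those higher that matched the annotation (2810055G20Rik did not), and it was 51.2% (Ubxn1) to 73.7% (Gm24270) in those lower, against a median of 49.0% over all genes. With GC and length corrected the log2 fold changes were 0.91 for Tet1, 0.39 for Prkdc, 1.11 for Gpr82, 0.41 for Elmo1, -0.53 for Lgals1, -0.39 for Cotl1 and -0.52 for Cndp2. The trend with GC of each library's deviations from the gene means (Spearman rho across genes) averaged 0.164 in PBS and -0.133 in NPC libraries (exact permutation p = 0.0571, n = 4 each). In GENCODE vM21 on mm10, Tet1 lies on chromosome 10 (62804570 to 62908996, minus strand), Prkdc on chromosome 16 (15637866 to 15842235, plus strand), Gpr82 on chromosome X (13661363 to 13667433, plus strand) and Lgals1 on chromosome 15 (78926725 to 78930465, plus strand). These spans cover the whole gene, introns included, and values are summed per gene.

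The precision bounded the size of a change in most genes, but moderate changes could be missed. In simulated reads with 200 changed genes the test recovered 67.0% of genes changed 2-fold and 24.4% of those changed 1.5-fold. Benjamini-Hochberg adjustment is stricter where fewer genes change, so these shares overstate recovery if few genes changed here. Tet1, with a log2 fold change of 1.17 (SE 0.20), did not pass. The median standard error of a log2 fold change was 0.19, and 79.1% of genes had a 95% interval that excluded a 2-fold difference in either direction. Without PBS 2 the count at an unadjusted p under 0.05 was 792, and with library weights it was 2139; without PBS 1 and NPC A together it was 1212. With each library corrected for GC content and transcript length, which left 11368 genes, the split was 351 higher and 728 lower. It was 735 higher and 652 lower over the 12256 uncorrected genes, so both the correction and the gene set differed. Of the 107 genes at an unadjusted p under 0.05 with at least a 2-fold difference, 96 were higher and 11 lower, against 120 higher and 44 lower at equal read depth and 67 higher and 26 lower after quantile normalization. Most of the 107 were low genes: 40 were counted with genes of mean under 1 left out, 9 (9 higher, 0 lower) under a stricter filter on low genes and 9 with 1 added on the linear scale.

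The series title names TGF-β2 secreted by neural precursor cells and the inflammatory program of these cells, and a panel of 17 genes was fixed for that question. None of the 15 panel genes in the table differed between groups (0 at an adjusted p under 0.05, adjusted over the panel alone or over all genes; smallest adjusted p over the panel alone 0.959). Tgfb2 and Il23a are not in the table used here. The inflammatory cytokine genes Il1b and Tnf were at 10.05 ± 0.71 and 6.48 ± 0.58 in PBS and 9.99 ± 0.70 and 6.57 ± 0.99 in NPC libraries (SD, n = 4), with log2 fold changes of -0.06 (95% interval -0.86 to 0.73) and 0.09 (-0.79 to 0.97). Nos2, which encodes inducible nitric oxide synthase, was at 7.24 ± 0.44 and 6.98 ± 0.72 (-0.27, interval -0.93 to 0.40), and its fold change turned positive with library weights. Arg1, the arginase gene often set against Nos2 as a sign of alternative activation, was at 10.01 ± 0.62 and 10.03 ± 0.84 (0.02, interval -0.81 to 0.84). The costimulatory genes Cd40, Cd80 and Cd86 had log2 fold changes of -0.04, 0.44 and 0.25. For 10 of the 15 genes the 95% interval excluded a 2-fold difference in either direction. Il6 (-0.07, interval -2.06 to 1.92), Il10 (0.05, interval -1.80 to 1.90), Il12b (-0.71, interval -2.69 to 1.26) and Tgfb3 (-0.68, interval -2.52 to 1.16) were too low and too variable for that. Cd80, which had 30 to 294 reads per library, did not exclude it either (0.44, interval -0.37 to 1.26). The fold change of Il12b changed sign without NPC A, and that of Tgfb3 without PBS 1 and NPC A together. Much of the spread lay in these libraries: Il6 was at -2.40 in PBS 1 and -4.09 in NPC A against the rest of each group, and Il10 at -3.15 and -3.18.

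On the receiving side, the TGF-β receptor genes were level: Tgfbr1 was at 8.79 ± 0.35 and 8.81 ± 0.11 and Tgfbr2 at 6.99 ± 0.27 and 6.98 ± 0.20 in PBS and NPC libraries. Tgfb1 was at 5.54 ± 0.10 and 5.30 ± 0.22 (-0.24, interval -0.52 to 0.04), and Smad7, an inhibitor induced by TGF-β signalling, at 4.10 ± 0.12 and 3.79 ± 0.60. Over the 25 measured genes of the TGF-β and SMAD response list, 10 were higher and 15 lower, with a median log2 fold change of -0.01 (camera adjusted p = 0.383, preset correlation). Its direction rested on single libraries: without PBS 1 (list mean 4.88) the median was -0.14 and the list passed as lower (adjusted p = 0.0239), while without NPC A (4.64) it turned to 0.08 (adjusted p = 0.702) and without PBS 4 to 0.04 (0.884). The 19 inflammatory cytokines and mediators had 10 genes higher and 9 lower, with a median of 0.05 (camera adjusted p = 0.874). Its sign too rested on single libraries. The median was -0.28 without NPC D (camera adjusted p = 0.190), -0.15 without PBS 1 (0.480) and -0.10 without PBS 3 (0.997). In that list Il12a was at 3.42 ± 0.58 in NPC and 2.69 ± 0.55 in PBS libraries, and Ptges, the inducible prostaglandin E synthase gene, at 2.42 ± 0.31 and 3.02 ± 0.53. No member of either list passed, over all genes or adjusted over the list alone.

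**Figure D2:**
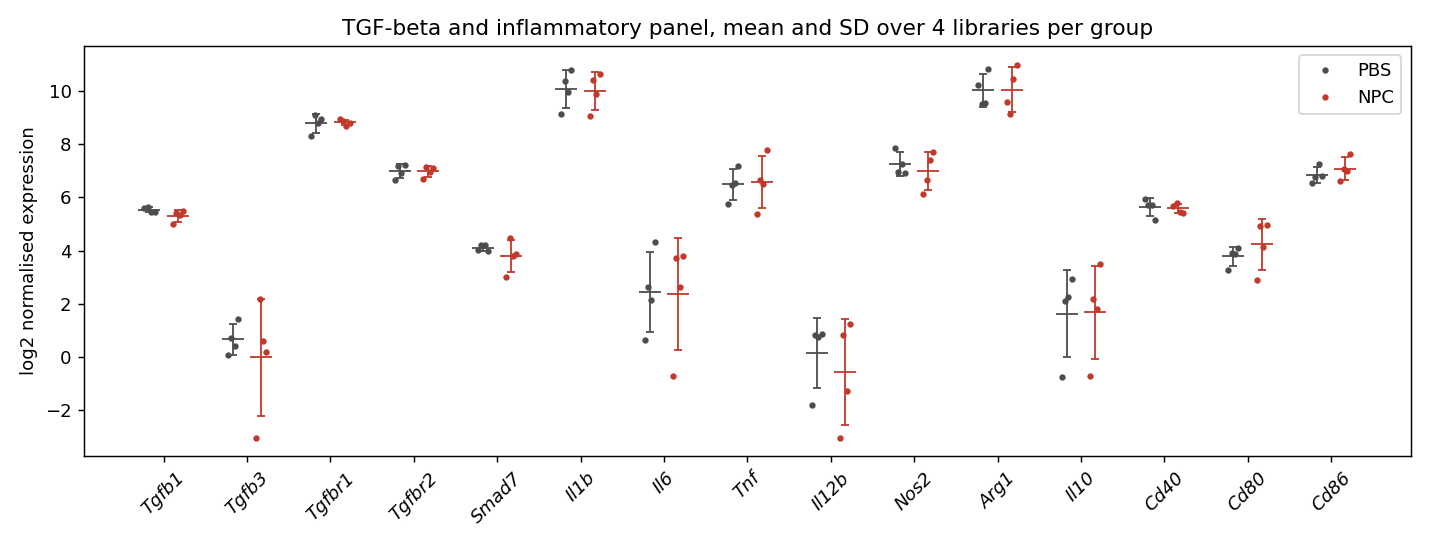
Log2 normalised expression of the 15 panel genes in the table, with 1 point per library, PBS in grey and NPC in red; horizontal marks are means and bars are SD over 4 libraries. The groups overlapped for each gene, and Tgfb3, Il6, Il12b and Il10 had the widest spread.

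Gene lists fixed in advance were then compared with all other genes by limma's camera test. Of 37 lists tested, 9 passed with the preset correlation of 0.01, 6 of them lower and 3 higher in NPC libraries. With the correlation estimated from these libraries (median 0.25 over the lists), 0 of the 37 passed, and the adjusted p was 0.925 for each of the 9. Fry and an exact permutation of the list means also called 0 lists (smallest adjusted p 0.589 and 0.634), so each direction below holds for the preset correlation alone.

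Genes of energy metabolism and translation lay lower in NPC libraries. Of the 53 measured nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase, 47 were lower and 6 higher, with a median log2 fold change of -0.21 (camera adjusted p = 3.92e-10 with the preset correlation, adjusted p = 0.925 with an estimated correlation). Uqcrq and Uqcrh, subunits of complex III, were at 4.90 ± 0.33 and 6.47 ± 0.34 against 5.43 ± 0.14 and 6.95 ± 0.13 in PBS (SD, n = 4), and Sdhc of complex II at 6.22 ± 0.19 against 6.58 ± 0.07. Of the 82 ribosomal protein genes, 69 were lower (median -0.20, and -0.30 without NPC B; camera adjusted p = 6.15e-08 with the preset correlation, adjusted p = 0.925 with an estimated correlation). Rpl29 was at 5.83 ± 0.24 against 6.29 ± 0.05. Ribosomal protein genes have many processed pseudogenes, and reads that match both cannot be assigned with certainty. In the glycolysis and hypoxia list 21 of 25 genes were lower (median -0.20, and -0.12 without NPC A; camera adjusted p = 5.28e-05, adjusted p = 0.925 with an estimated correlation). There Pgk1, Tpi1 and Pkm, enzymes of glycolysis, had log2 fold changes of -0.46 (SE 0.12), -0.42 (SE 0.12) and -0.42 (SE 0.14). Pgk1 was the 1 gene of the list that passed adjusted over the list alone (limma adjusted p = 0.0413). No member of the oxidative phosphorylation or ribosomal list passed in that way. That adjustment, also used below, does not allow for the number of lists: 3 of the 37 had a member that passed it. Over all genes the smallest adjusted p was 0.382. The list means of oxidative phosphorylation were 5.14 ± 0.09 in PBS and 4.91 ± 0.19 in NPC libraries (exact permutation p = 0.0571, n = 4 each), those of glycolysis 6.99 ± 0.04 and 6.80 ± 0.15 (exact p = 0.0857), and those of ribosomal protein genes 5.34 ± 0.12 and 5.17 ± 0.19 (exact p = 0.229). Without NPC B, at 5.45 against 5.05 to 5.11 in the other NPC libraries, the ribosomal difference went from -0.16 to -0.26, and without NPC D that of oxidative phosphorylation went from -0.24 to -0.16.

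Genes of protein folding and lysosomes were lower by smaller margins, and those of class I presentation by a similar margin but less stably. In the unfolded protein and amino acid stress list 17 of 26 genes were lower (median -0.12, camera adjusted p = 0.00135; 0.101 without NPC A). The median was -0.06 without PBS 2, -0.23 without PBS 1 and -0.20 without NPC B. The chaperone and disulfide isomerase genes Manf (-0.54), Pdia6 (-0.47) and Pdia4 (-0.35) had the smallest p, with non-overlapping groups. Of 20 class I pathway genes 15 were lower (median -0.24, camera adjusted p = 0.00182), among them Tapbp, the gene of the peptide-loading protein tapasin (-0.46, SE 0.15), and H2-T22 (-0.50, SE 0.16); after GC and length correction the adjusted p was 0.0875, and the median was -0.12 without PBS 1 and -0.13 without NPC D. Many class I genes are near-identical copies, so that reads cannot always be assigned to 1 of them. Of 32 lysosomal genes 20 were lower (median -0.07, camera adjusted p = 0.0358), and Hexa, the gene of the hexosaminidase alpha subunit, passed adjusted over the list alone (7.93 ± 0.11 against 8.42 ± 0.12; adjusted p = 0.0256). The lysosome list lost its call in 11 of 21 alternatives, and its median was 0.01 without PBS 4, 0.00 without NPC A, -0.04 without NPC B, -0.11 without PBS 1 and -0.12 without NPC D. With an estimated correlation the adjusted p was 0.925 for these 3 lists too.

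**Figure D3:**
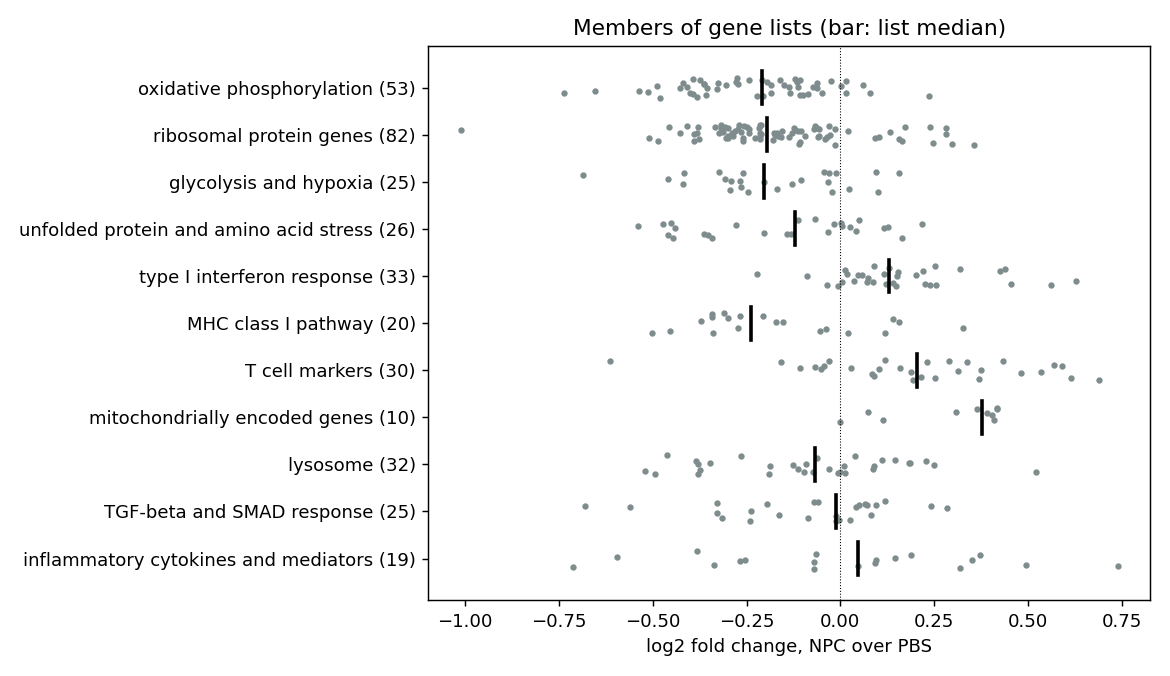
Log2 fold change (NPC over PBS) of each measured member, 1 point per gene, for the 9 lists that passed with the preset correlation and for the TGF-β and inflammatory cytokine lists; black bars are list medians and the number of genes is in brackets. Medians ran from -0.24 for the class I pathway to 0.38 for mitochondrially encoded genes, and lay at -0.01 and 0.05 for the TGF-β and cytokine lists.

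Interferon-stimulated genes, T cell markers and mitochondrially encoded genes lay higher in NPC libraries. Of 33 type I interferon response genes 29 were higher, with a median log2 fold change of 0.13 (camera adjusted p = 0.00182 with the preset correlation, adjusted p = 0.925 with an estimated correlation). Ifi44, Herc6 and Ifih1, the last encoding the RNA sensor MDA5, had log2 fold changes of 0.63 (SE 0.14), 0.44 (SE 0.12) and 0.43 (SE 0.12), and 3 genes of the list passed adjusted over the list alone. The list did not pass without PBS 4 (adjusted p = 0.162, median 0.03) or without NPC A (0.0546), and its median was 0.22 without NPC D. The 31 genes of the interferon-gamma response were not shifted (median 0.03, adjusted p = 0.848).

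Among 30 T cell markers 23 were higher (median 0.20, camera adjusted p = 0.00626), including Cd4 (4.42 ± 0.39 against 3.81 ± 0.10); none passed adjusted over the list alone, and the list did not pass without NPC B (median 0.10, adjusted p = 0.359). Of 10 mitochondrially encoded genes 9 were higher (median 0.38, camera adjusted p = 0.0226), with mt-Nd4 at 10.62 ± 0.31 against 10.21 ± 0.33. That list lost its call without PBS 3 (median 0.17, adjusted p = 0.452), the library with the lowest mitochondrial share, without NPC B (0.0521), without NPC D (0.0852) and after GC and length correction (0.287). With an estimated correlation the adjusted p of both lists was 0.925. As a share of all reads, mitochondrially encoded transcripts were level, at 30.4 ± 7.9% in PBS and 30.7 ± 4.0% in NPC libraries (exact permutation p = 0.971). The ribosomal RNA gene mt-Rnr2, which held 20.6% and 19.8% of reads on average, had a log2 fold change of -0.0004.

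The remaining lists did not pass. Costimulation and checkpoint ligands had 12 of 14 genes higher (median 0.20, camera adjusted p = 0.113). They passed without NPC A (0.0147), without PBS 1 and NPC A together (0.0262) and with a residual component as covariate (0.0426), and had a median of 0.06 without NPC D (0.283). The 22 dendritic cell genes had a median of 0.19 (adjusted p = 0.403) that turned to -0.05 with library weights and -0.16 without NPC B, whose list mean was 5.09 against 3.53, 3.80 and 3.74 in NPC A, C and D. The medians were 0.16 for 20 chemokines (0.479), 0.15 for 15 class II genes (0.636), -0.06 for 19 inflammatory monocyte genes (0.636), -0.06 for 22 genes of alternative activation and repair (0.687), -0.03 for 26 NF-κB targets (0.636), -0.01 for 23 chemokine and homing receptors (0.876) and -0.00 for 23 matrix and protease genes (0.857). For chemokines the median was 0.41 without NPC A (adjusted p = 0.0104), 0.01 without PBS 1 (0.792) and 0.02 without NPC D (0.828), the last 2 with camera's direction turned to lower. That of alternative activation and repair turned to 0.20 without NPC A (camera adjusted p = 0.317) and 0.12 without PBS 4 (0.423). Lipid handling and efflux (-0.05, adjusted p = 0.354; 0.0434 without NPC D), cholesterol biosynthesis (-0.11, 0.402), pattern recognition receptors (0.03, 0.402) and complement and Fc receptors (0.00, 0.565) did not pass either. Nor did the cell cycle (0.13, 0.383; -0.02 with library weights; adjusted p = 0.0388 without NPC D), phagocyte activation in neurodegeneration (-0.08, 0.381; 0.0143 without PBS 1) or the immediate-early and heat-shock genes (-0.07, 0.359). The immediate-early list went both ways: it passed as lower without PBS 1 (median -0.44, adjusted p = 1.44e-07), without NPC B (-0.26, 0.0273) and with library weights (-0.21, 0.0264), and turned to 0.22 without NPC A (0.104), 0.11 without PBS 4 (0.928) and 0.06 without PBS 2 (0.642). Of the 28 lists that did not pass, the median of 17 changed sign without 1 library and that of 11 under another alternative. With GC and length corrected it was -0.02 for inflammatory cytokines, -0.04 for the interferon-gamma response and 0.04 for NF-κB targets.

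Markers of other cells of blood and nervous tissue were compared in the same way, and besides T cells none passed. The gate on CD45-high, CD11b-positive and Ly6G-negative cells should remove neutrophils, cells of the neural lineages and most microglia. Microglia markers had a median of 0.18 (16 genes, adjusted p = 0.321), neutrophil markers 0.18 (13 genes, 0.443; 0.00343 without NPC D, and a median of 0.02 without PBS 3) and B and plasma cell markers 0.29 (10 genes, 0.337; -0.03 without NPC B). The values were 0.29 for natural killer cells (9 genes, 0.494; -0.02 without NPC B), 0.17 for plasmacytoid dendritic cells (7 genes, 0.361), 0.17 for border and tissue macrophages (7 genes, 0.636), 0.13 for neural precursors and astrocytes (9 genes, 0.636; -0.04 with GC and length corrected and -0.08 with low genes left out) and 0.16 for oligodendrocytes and neurons (8 genes, 0.876; -0.03 at equal depth). The microglia list passed as higher without NPC A (median 0.36, adjusted p = 0.0104), without PBS 4 (0.30, 0.00912) and with a residual component as covariate (0.0426), while without PBS 1 the median was 0.02 and camera's direction lower (0.861). The border and tissue macrophage median was 0.03 without NPC D (camera adjusted p = 0.920) and 0.06 without PBS 1 (0.977), both with camera's direction lower. Lists of endothelial cells and pericytes, erythroid cells, sex-linked genes, and mast cells and basophils had 4, 4, 1 and 1 genes in the table and were not tested.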

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

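All tests of explanations in this part were chosen after the results were seen, and those for PBS 1 and NPC A and for the gene lists were redefined once after a first version had been run. The first version for the lists asked for a corrected difference over 2 SE, which the ribosomal and T cell lists did not reach before any correction; it left both lists open, and glycolysis for GC and length. The second asks whether the shift a correction makes, plus 2 SE of that shift, stays under 50% of the difference, with the list still past the camera threshold at the preset correlation. Groups of 4 libraries were searched for 1 library far from the other 3 by Dixon's ratio (95% level); of 394 groups 19 met this, where chance gives about 20, and 11 of the 19 were in PBS 1 or NPC A. Among library measures, the mitochondrial share of PBS 3 met it, at 18.6%. NPC C had the lowest share of the NPC libraries, 25.2%, but did not meet it.

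PBS 1 and NPC A stood apart together in the immediate-early and heat-shock genes, with list means of 5.74 and 5.69, a fall of 1.56 and 1.51 on the log2 scale against the other 3 libraries of each group. Across all 12256 genes their deviations from the rest of their group correlated at r = 0.53, against at most 0.25 in the other 15 pairings of a PBS and an NPC library (genes are not independent replicates). The number of reads was argued against, since with reads thinned to equal depth PBS 1 was still at -1.57 and NPC A at -1.42 (SD of the other libraries 0.14 and 0.15). GC content was argued against too, since after correction the values were -1.63 and -1.47. Fewer microglia, cells that a CD45-high gate would mostly remove, would lower no gene by more than genes made by microglia alone. On average 5 microglia genes (P2ry12, Gpr34, Siglech, Sall1, Tmem119) fell by 1.03 in both. The immediate-early list lay a further -0.54 and -0.48 below them (SD 0.24 and 0.20). However, P2ry12 was at -0.79 in PBS 1 and -1.37 in NPC A, and Siglech at -1.41 and -0.53. Siglech is also in the plasmacytoid dendritic cell list, and transcription of these genes in other sorted cells would make their fall smaller. Fewer microglia therefore stay open, and loss of other cell types was not tested. No biological explanation was tested, as the design names no group these libraries share; handling or the day of the sort may differ, but the labels give neither.

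The lower oxidative phosphorylation, ribosomal and glycolysis lists were weighed against GC and length bias and against depth, each as the cause of most of the difference. The number of reads was argued against for all 3. With reads thinned to equal depth the list means differed by -0.22 (oxidative phosphorylation, -0.24 before), -0.15 (ribosomal, -0.16 before) and -0.19 (glycolysis, -0.18 before). The shifts towards 0 were 0.01, 0.02 and -0.01 (SE 0.01, 0.02 and 0.01), with camera adjusted p of 2.95e-08, 1.56e-06 and 9.81e-05. Thinning changes counts alone and moves well-counted genes little. Other differences that came with depth, which went together with treatment, therefore stay open. GC and length bias was argued against for oxidative phosphorylation (-0.24 before, -0.23 after; shift 0.01, SE 0.02; adjusted p = 8.66e-08) and glycolysis (-0.18 and -0.16; shift 0.02, SE 0.02; adjusted p = 0.00127). For ribosomal protein genes (-0.17 before, -0.13 after, adjusted p = 0.000323; -0.26 without NPC B and uncorrected) the shift of 0.04 (SE 0.03) plus 2 SE came to 0.0862, against 0.0848 for 50% of the difference, so bias is argued against as the whole cause and stays open as the cause of a large part. Treatment stays open for all 3 and untested apart from chance, which could not be excluded. By exact permutation of their own list means, p was 0.0571 (oxidative phosphorylation), 0.0857 (glycolysis) and 0.229 (ribosomal). Counting lists of any kind, 27 of the 35 splits of the 8 libraries gave at least the real 9, and the highest other split gave 26. That count does not measure how often these 3 lists shift.

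The higher T cell marker list (mean difference 0.21, SE 0.12, and 0.10 without NPC B) may come from more T cells or T cell RNA in the NPC sorts, which a gate on CD11b and Ly6C should exclude. NPC B had a list mean of 3.36, against 2.98, 2.81 and 2.98 in NPC A, C and D. It also had the highest means of the 8 libraries in natural killer (3.06) and B and plasma cell markers (2.64). The same held for dendritic cell genes (5.09), microglia (5.21) and plasmacytoid dendritic cell markers (4.69), so its high values were not confined to lymphocyte markers. NPC B was also the shallowest library (2653818 reads). The 10 T cell receptor complex and signalling genes had a median log2 fold change of 0.0929, with 6 higher (Cd3e 0.43, Cd3d 0.54) and 4 lower (Zap70 -0.61), so members went both ways and this stays open; some dendritic cells also transcribe Cd4. The number of reads was argued against as the cause of most of the difference (0.19 at equal depth, shift 0.02, SE 0.03, camera adjusted p = 0.0183). So were GC and length (0.19 after correction, shift 0.01, SE 0.02, camera adjusted p = 0.000596). Other differences that came with depth were not tested by thinning.

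The other single-library values were as follows. PBS 1 was low in the stress response list (unfolded protein and amino acid stress, mean 6.34), in plasmacytoid dendritic cell markers (3.68), Havcr2 (6.31), Il12b (-1.81) and Tlr3 (4.59), and high in Il4ra (7.04) and S100a6 (7.37). NPC A was low in Havcr2 (6.76) and Rpl29 (5.48). NPC B was high in ribosomal protein genes (mean 5.45) and Ccna2 (2.77) and low in Elmo1 (6.37). PBS 4 was low in Bahd1 (4.09) and high in Pf4 (2.42), PBS 3 was high in Itgax (7.50), and NPC C was low in Plau (4.90).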

How the results depend on the processing

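Voom weights, equal depth, GC and length correction, leaving out PBS 1 and NPC A together and the permutation of list means were chosen after seeing the data. No gene passed under any setting (0 genes), and all 35 splits also gave 0 (highest other 0). The 1387 genes at an unadjusted p under 0.05 became 2139 with library weights and 792 to 1846 when 1 library was left out; 2 of the 35 splits gave as many, the highest other 1561 with PBS 1, NPC A, NPC C and NPC D on one side, so chance could not be excluded. The 9 gene lists became 0 with an estimated correlation, 0 with fry and 0 with permuted list means, 7 to 12 without 1 library and 6 after GC and length correction; the cause was not tested. The exact p of principal component 1 was 0.114 to 1 and that of component 2 was 0.0286 to 1 without 1 library, the lowest without NPC B and the smallest 7 libraries allow. Oxidative phosphorylation, ribosomal and glycolysis lists passed in 21 of 21 alternative fits with the preset correlation. The class I pathway, the T cell list and the unfolded protein and amino acid stress list passed in 20. Of the 154 genes chosen by rule, at most 24 moved by over 1 SE (GC and length correction) and at most 9 changed sign (without NPC A). No paired analysis was made because the groups share no replicate names. A pairing by order, PBS 1 with NPC A and so on, was not tested and stays open. PBS 3 and NPC C also had the lowest mitochondrial shares of their groups, 18.6% and 25.2%. By Pearson correlation, PBS 1, PBS 3 and PBS 4 were closest to NPC A, NPC C and NPC D among the NPC libraries. PBS 2 was closest to NPC C (0.972, against 0.971 for NPC B), and by chi-square PBS 4 was closest to NPC B (5.22 per degree of freedom). All intervals and tests here take the libraries as unpaired and could differ if the pools were in fact paired. Few reads limit the low genes: Il12b, Il10, Il6 and Tgfb3 had 0 to 2 reads in their lowest library. Depth was not the only limit, since PBS 1, with 15746650 reads, had Il6 at -2.40 and Il10 at -3.15 against the other PBS libraries.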

Other observations

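Integrin and inflammasome genes not described above showed small differences within lists that did not pass. Itga4, the alpha4 integrin used in entry to the central nervous system, was at 9.31 ± 0.13 in NPC and 8.95 ± 0.19 in PBS libraries (SD, n = 4), and its partner Itgb1 at 8.44 ± 0.11 and 8.74 ± 0.09, without overlap between groups in either gene. Of 18 inflammasome and pyroptosis genes 12 were higher, with list means of 5.97 ± 0.05 and 5.86 ± 0.04 (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.634 over 37 lists). Aim2, a cytosolic DNA sensor gene, was at 6.84 ± 0.22 against 6.38 ± 0.16. Among lipid handling genes, Fabp5 (-0.41, SE 0.11), Abcg1 (-0.32, SE 0.11) and Npc2 (-0.38, SE 0.13) were lower without overlap, and Lpl was at 0.47 (SE 0.23). The adjusted p of each of these genes in limma was over 0.38.

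Besides immediate-early genes, the libraries PBS 1 and NPC A were low in chemokines (-1.07 and -1.14 against the other 3 libraries of each group), inflammatory cytokines and mediators (-0.83 and -1.06) and dendritic cell genes (-0.71 and -0.68). Markers of some other cell types fell in both too: microglia (-0.81 and -0.67), B and plasma cells (-0.78 and -0.64) and border and tissue macrophages (-0.59 and -0.67). Neutrophil markers were at 0.19 and 0.37, natural killer cell markers at 0.03 and 0.51 and T cell markers at 0.15 and -0.07. Cxcl1 lay at -5.07 and -4.09, Egr1 at -2.94 and -3.17, and Il1b at -1.25 and -1.25. The interferon-gamma response was at 0.41 and 0.20.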
